A study of Mus musculus with 20 samples.

How the data were processed

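The data were RNA-seq gene tables of 20 libraries, 1 per library, from mouse fetal liver progenitor cells without mature lineage markers after 3 days of culture with a retroviral vector. Per the labels, total RNA was prepared with the NuGEN Ovation protocol, and per the submitters' processing notes STAR 2.5.2b and RSEM 1.3.0 were used on the genome build mm10. The deposited files hold, per gene, the expected count, which is the number of reads that RSEM assigns to a gene and is fractional where reads map to more than 1 gene, and in the same deposited tables the TPM and FPKM, which the authors made with RSEM by scaling to gene length and library total. The expected counts, rounded to whole numbers, were used for all main results, and TPM in 1 alternative. FPKM and the transcript names in the same tables were not analysed here. Of 53379 gene identifiers 53274 had a symbol in GENCODE M21 (GRCm38), and the 105 without one held at most 0.015% of the counts of any library. Library totals ran from 22330475 to 33245876 expected counts, and no 2 libraries of a group were duplicates, with a chi-square per degree of freedom of 14.6 to 70.8 between replicates.

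Groups were taken from the sample labels: wild-type with an empty vector, enhancer-null with an empty vector, and enhancer-null with GATA2, R307W or T354M, with 4 libraries each. The file names of the wild-type GATA2 group do not name the enhancer-null genotype, and the labels were followed. The records of the R307W and T354M libraries carry less protocol text than those of the other 3 groups, so a difference in handling between these sets of libraries cannot be separated from the comparisons of a variant with the other groups. Counts of Gata2 cannot separate reads of the vector's coding sequence from those of the gene, and the labels do not give the sequence in the vector.

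Genes were filtered with filterByExpr, which left 15835, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 20 libraries were in 1 fit with 5 group means, 15 residual degrees of freedom and a common dispersion of 0.0468. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The SE of a log2 difference is its size divided by the square root of F. Where a group had no counts, the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only. The 8 comparisons were enhancer-null against wild-type, each vector against the empty vector in enhancer-null cells, each variant against wild-type GATA2, R307W against T354M, and wild-type GATA2 in enhancer-null cells against wild-type cells.

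A set of 17 gene lists was fixed from general knowledge: erythroid, megakaryocyte, mast cell and basophil, eosinophil, monocyte and macrophage, neutrophil, dendritic cell and MHC class II, lymphoid, stem and progenitor, interferon response, innate immune receptors, cell cycle, immediate early and heat shock, mitochondrially encoded, hepatocyte, endothelial and stromal, and chromosomal neighbours of Gata2. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. Adjustment was over the lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone.

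Genes were named by a rule: Gata2, then for enhancer loss and the 3 vector comparisons the 6 genes with the highest and the 6 with the lowest log2 difference among those called, with a mean of at least 5 CPM in 1 group and all 4 libraries of one group above all 4 of the other, leaving out predicted, ribosomal, mitochondrial and pseudogene symbols. From each list with a called member the 2 with the lowest adjusted p were added. For the other 4 comparisons the 4 highest and 4 lowest were named beside genes named before. The comparisons, lists, rule, tests and most alternatives were fixed before the data were examined.

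Genes changed by enhancer loss and moved back by a vector, and genes changed by wild-type GATA2 that differ under a variant, were counted from calls with opposite signs. As these comparisons share libraries, each count was set beside the number that independent lists would share, beside the number and the covariance in 20 simulations without an effect, and beside the median over the 6 ways to split the shared libraries 2 and 2.

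Alternatives were DESeq2 size factors, no filter on low counts, the replicate number as a block, only the 8 libraries of a comparison, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1), a fold change of at least 2, an estimated correlation or fry for the lists, and leaving out each library in turn. A block over the 16 enhancer-null libraries, leaving out replicate 4 of all groups, and nuclear protein-coding genes alone were added after the data were seen, the others were fixed with the tests. Whether the replicate numbers pair the libraries was checked from correlations across genes of the residuals of same-numbered libraries. These exceeded 0.1 for all 4 numbers between wild-type GATA2 and the empty vector (0.11 to 0.26) and among the 3 vector groups (lowest 0.14, highest 0.65), but not between the other groups. The Y-linked gene Ddx3y had the same pattern over numbers 1 to 4 in the 4 enhancer-null groups, with 0 CPM in number 4, and another one in wild-type cells. So the numbers were taken to pair the 4 enhancer-null groups with each other and not with wild-type cells. For R307W and T354M against the empty vector this was decided from Ddx3y after the blocked calls had been seen. The medians of all genes under TMM and size factors lay within 0.1 of 0 on the log2 scale. On data simulated from these libraries with 15835 genes, the fit recovered 79 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and called 5 unchanged genes.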

Results

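Gene expression was measured by RNA-seq in blood progenitor cells of mouse fetal liver, taken as cells without markers of mature lineages, infected with a retroviral vector and kept in culture for 3 days with interleukin 3 and stem cell factor. Gata2 encodes a zinc finger transcription factor of blood stem and progenitor cells, and a distal enhancer 77 kb upstream of the gene drives its expression in progenitors. The 20 libraries formed 5 groups of 4: wild-type cells with an empty vector, and cells lacking the enhancer (enhancer-null cells) with an empty vector, with wild-type GATA2, or with GATA2 carrying the protein change R307W or T354M. R307W lies in the N-terminal zinc finger and T354M in the C-terminal one, which binds DNA, and T354M is a recurrent inherited variant in families with myelodysplasia and acute leukaemia. Each library held 22330475 to 33245876 expected counts, and 17.9 to 24.6% of them came from the mitochondrial ribosomal RNA mt-Rnr2. Of 53379 gene identifiers 15835 had enough counts to be tested. The labels do not say whether replicates come from separate cultures or animals, so every p-value measures the spread between these libraries. The replicate numbers were taken to pair the enhancer-null groups, from the pattern of Ddx3y, but the main counts and p-values do not use that pairing. Values with the replicate number as a block are given as an alternative. Values below are TMM-scaled CPM as mean ± SD of 4 libraries per group, log2 differences carry a standard error (SE), and adjusted p-values are from edgeR unless a gene list is named.

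On the first axis of a principal component analysis, with 35.4% of the variance, the 4 wild-type libraries lay at one end and the 4 enhancer-null libraries with an empty vector at the other. The 12 libraries with a GATA2 vector lay between them on that axis. The second axis held 21.5%, and on it the replicate 4 library of each of the 3 vector groups was the lowest of its group. In those 12 libraries, 2969 genes differed between replicate 4 and replicates 1 to 3, 1345 higher and 1624 lower. In replicate 4 Gata2 was higher, by 0.95 on the log2 scale (edgeR adjusted p = 0.00545), as were 23 of 34 erythroid and 18 of 23 mast cell and basophil genes. All 30 interferon response genes and all 13 hepatocyte genes were lower in replicate 4, with median log2 differences of -1.61 and -2.03.

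**Figure D1:**
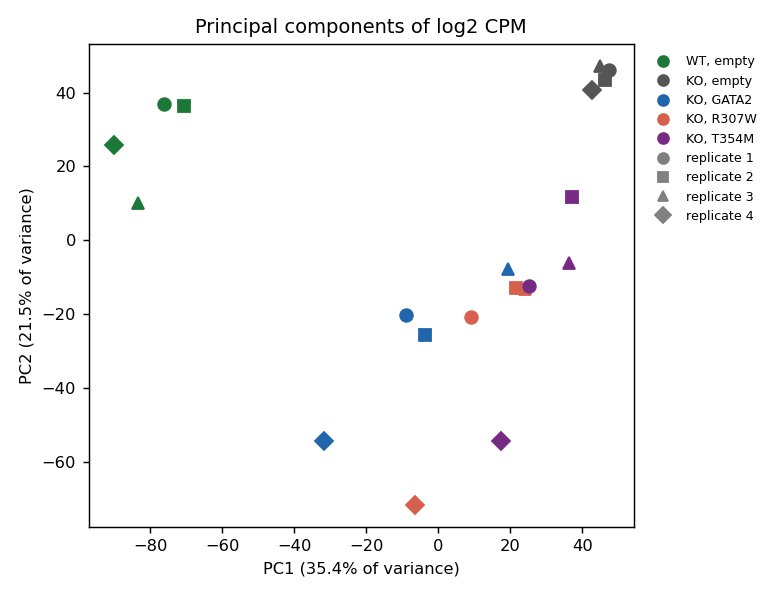
Principal component scores of the 20 libraries from log2 CPM, first axis across and second axis up, with 1 point per library coloured by group, where WT is wild-type and KO is enhancer-null. The wild-type libraries lie between -90.2 and -70.6 on the first axis, and the replicate 4 libraries of the 3 vector groups lie between -71.5 and -54.2 on the second.

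The effect of the enhancer was read from enhancer-null against wild-type cells, both with an empty vector. Gata2, on chromosome 6 from 88193891 to 88207032 of GRCm38, fell from 44.3 ± 9.81 to 5.79 ± 1.3 CPM (n = 4 and 4), 7.63-fold. All 10 eosinophil genes, 19 of 23 mast cell and basophil genes and 32 of 34 erythroid genes fell. Epx, which encodes eosinophil peroxidase, fell from 69.5 ± 8.67 to 0.114 ± 0.129 CPM, and Gata1, the GATA factor of the erythroid and megakaryocyte lineages, from 90.7 ± 9.20 to 5.52 ± 1.31. Tpsb2, a mast cell tryptase, had 15.6 ± 4.18 CPM in wild-type cells and no counts in enhancer-null cells, at least 536-fold lower with a floor of 3 counts over the group. Of the interferon response genes 29 of 30 rose, with 23 of 28 monocyte and macrophage and 14 of 16 dendritic cell and MHC class II genes. Ifit3 rose from 3.84 ± 3.46 to 84.6 ± 25.6 CPM and Siglech, a surface receptor of plasmacytoid dendritic cells, from 0.163 ± 0.129 to 7.03 ± 0.877.

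In all, 6859 genes changed on loss of the enhancer, 43.3% of those tested, 3181 up and 3678 down, and 2972 of them changed at least 2-fold. The log2 difference for Gata2 was -2.93 (SE 0.36, adjusted p = 2.88e-06), for Epx -9.26 (SE 0.77, adjusted p = 2.74e-08), for Gata1 -4.03 (SE 0.38, adjusted p = 1.44e-07) and for Prg2, an eosinophil granule protein, -7.34 (SE 0.60, adjusted p = 2.64e-08). Cd7 rose by 4.92 on the log2 scale (SE 0.50, adjusted p = 3.32e-07), Siglech by 5.46 (SE 0.79, adjusted p = 1.77e-05) and Ifit3 by 4.48 (SE 0.66, adjusted p = 2.14e-05). For each gene named in this comparison, all 4 libraries of one group lay above all 4 of the other. The small nucleolar RNA Rnu3b, whose 4 near-identical copies share reads, also fell, with an uncertain level for each copy. Of 92 named genes, 5 were no longer called when some single library was left out, and none of those 5 is given a value here.

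Of the 34 erythroid genes tested, 32 fell (1 up and 32 down adjusted over the list alone), among them the haem enzyme gene Fech, 6.70-fold, and the anion exchanger gene Slc4a1, 31.3-fold (camera adjusted p = 1.51e-22, and adjusted p = 0.238 with an estimated correlation). All 10 eosinophil genes fell, with the same 10 adjusted over the list alone (camera adjusted p = 8.83e-09, and adjusted p = 0.238 with an estimated correlation). Of 23 mast cell and basophil genes, 19 fell and 4 rose, and the counts were the same adjusted over the list alone. The histamine enzyme gene Hdc fell from 239 ± 20.0 to 14.2 ± 1.46 CPM and the carboxypeptidase gene Cpa3 fell 23.1-fold (camera adjusted p = 2.22e-07, and adjusted p = 0.238 with an estimated correlation). Of 21 megakaryocyte genes 17 fell and 1 rose, as they did adjusted over the list alone, with Clec1b 3.98-fold lower (camera adjusted p = 4.9e-06, and adjusted p = 0.238 with an estimated correlation). Among 24 neutrophil genes 15 fell and 3 rose (16 and 3 adjusted over the list alone), including the granule gene Camp, 7.73-fold lower, and the transcription factor gene Gfi1, 2.45-fold lower (camera adjusted p = 0.00137, and adjusted p = 0.34 with an estimated correlation). Among 30 cell cycle genes 18 fell, and 18 adjusted over the list alone, with the cyclin gene Ccne1 2.60-fold lower (camera adjusted p = 3.45e-05, and adjusted p = 0.238 with an estimated correlation).

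Interferon response genes moved the other way: 29 of 30 rose (30 adjusted over the list alone), with Bst2 4.33-fold higher (camera adjusted p = 1.86e-13, and adjusted p = 0.238 with an estimated correlation). Of 28 monocyte and macrophage genes 23 rose (24 adjusted over the list alone), including the chemokine receptor gene Cx3cr1, 7.78-fold (camera adjusted p = 3.43e-08, and adjusted p = 0.238 with an estimated correlation). Of 16 dendritic cell and MHC class II genes 14 rose and 2 fell, the same counts adjusted over the list alone, and Itgax was 9.09-fold higher (camera adjusted p = 1e-07, and adjusted p = 0.238 with an estimated correlation). Of 25 innate immune receptor genes 18 rose (19 adjusted over the list alone), with Tyrobp 2.38-fold higher (camera adjusted p = 3.97e-07, and adjusted p = 0.253 with an estimated correlation). Of 10 lymphoid genes 8 rose, and 8 adjusted over the list alone, including Cd79b, 3.44-fold (camera adjusted p = 0.000254, and adjusted p = 0.238 with an estimated correlation).

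The other 6 lists were not called for loss of the enhancer. Stem and progenitor genes split, 8 up and 8 down of 20 and the same adjusted over the list alone, with Tal1 4.67-fold lower (camera adjusted p = 0.707). Of 18 immediate early and heat shock genes 7 rose and 4 fell, 8 and 4 adjusted over the list alone (camera adjusted p = 0.259, but called as higher with no filter on low counts, 0.0201). Of 13 mitochondrially encoded genes 1 rose and 2 fell, with 2 down adjusted over the list alone (camera adjusted p = 0.707). Of 13 endothelial and stromal genes 4 rose and 1 fell, with 4 up adjusted over the list alone (camera adjusted p = 0.055). That list was called as higher with no filter on low counts (0.00124), with the 8 libraries alone (0.0411), and without enhancer-null empty-vector replicate 3 (0.0388) or wild-type replicate 1 (0.0484) or 4 (0.046). The list of hepatocyte genes, a marker of another liver cell type, had camera adjusted p = 0.359. Of 11 tested genes that neighbour Gata2 on chromosome 6, 2 rose and 2 fell, and the same adjusted over the list alone (camera adjusted p = 0.939). Among these neighbours, Mgll, a monoglyceride lipase gene 531 kb from the start of Gata2, fell from 21.3 ± 3.54 to 2.41 ± 0.171 CPM, 8.82-fold (adjusted p = 7.75e-10).

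**Figure D2:**
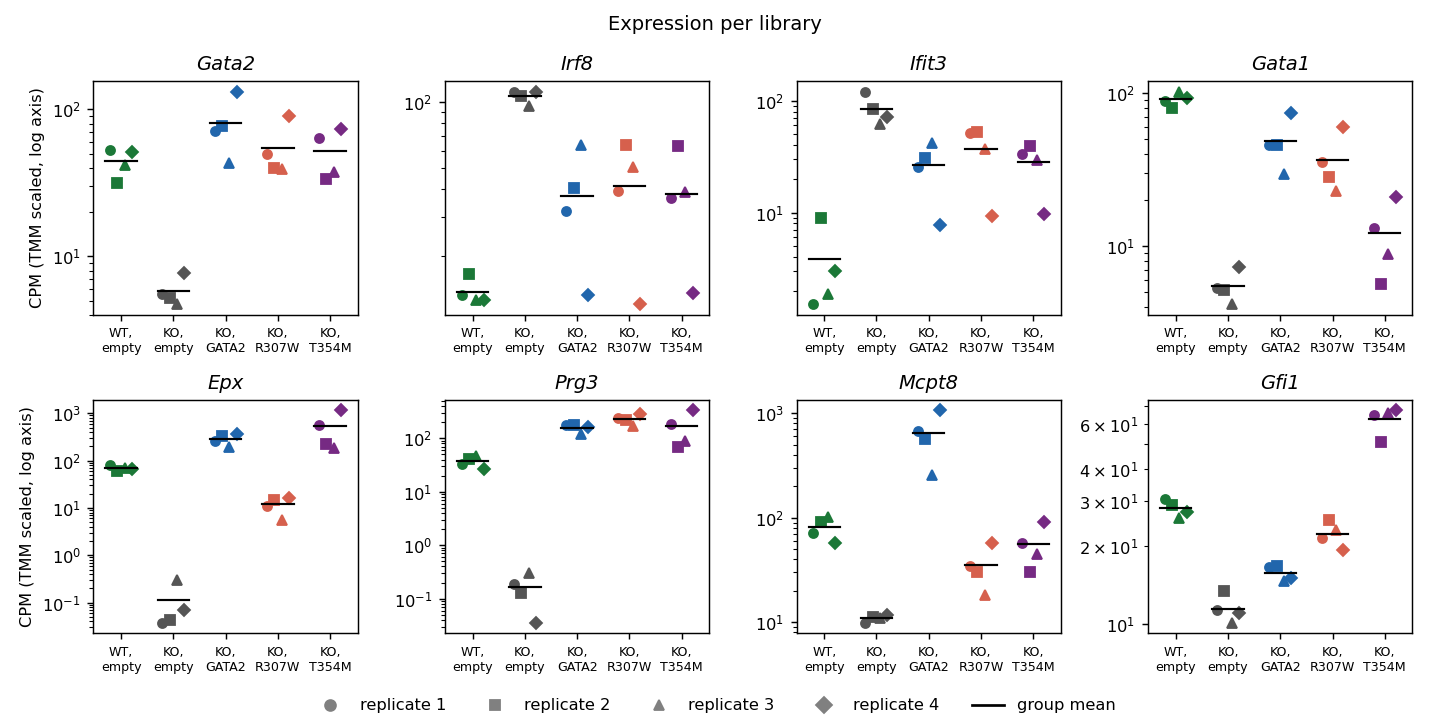
CPM on a log axis of 8 genes in the 20 libraries, 1 point per library in each of the 5 groups, with a black bar at the group mean. Epx was at 0.114 CPM in enhancer-null cells with an empty vector and at 287, 11.9 and 536 CPM with wild-type GATA2, R307W and T354M.

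Wild-type GATA2 in enhancer-null cells, against the same cells with an empty vector, asked what restoring the factor changed. Gata2 counts were 80.7 ± 37.3 CPM with the vector and 5.79 ± 1.3 without (n = 4 and 4), 13.9-fold, and these counts cannot separate vector from endogenous transcripts. All 10 eosinophil genes rose, with Epx at 287 ± 74.4 CPM against 0.114 ± 0.129 and Prg2 660-fold higher. So did 19 of 23 mast cell and basophil genes, including the basophil protease gene Mcpt8 from 10.9 ± 0.786 to 644 ± 337 CPM and Hdc to 568 ± 262 CPM. Among interferon response, monocyte and macrophage, and dendritic cell genes 23 of 30, 16 of 28 and 13 of 16 fell. Bst2 fell 2.04-fold and Itgax 2.57-fold.

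A total of 3042 genes changed with wild-type GATA2, 19.2% of those tested, 1738 up and 1304 down, with 1340 at least 2-fold. With the replicate number as a block the total was 4085, and 3037 of the 3042 were among them. Log2 differences were 3.80 for Gata2 (SE 0.37, adjusted p = 2.41e-06), 11.30 for Epx (SE 0.78, adjusted p = 3.31e-08), 5.88 for Mcpt8 (SE 0.46, adjusted p = 2.12e-07) and 3.13 for Gata1 (SE 0.37, adjusted p = 1.49e-05). Among genes that fell were Mycl, at -1.98 (SE 0.49, adjusted p = 0.00894) and the smooth muscle actin gene Acta2, at -1.89 (SE 0.37, adjusted p = 0.00158). For each gene named here except Il7r and Mgll, all 4 libraries of one group lay above all 4 of the other. Without GATA2 replicate 4 the total was 1588 genes, and 27 of the 84 named genes called were no longer called, although the genes given values here kept their calls. Without replicate 4 of every group the total was 1998.

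All 10 eosinophil genes rose, and 10 adjusted over the list alone, and this list held under both correlations (camera adjusted p = 1.48e-20, and adjusted p = 0.0494 with an estimated correlation). Of 23 mast cell and basophil genes 19 rose and 1 fell (20 and 2 adjusted over the list alone; camera adjusted p = 2.03e-19; adjusted p = 0.0622 with an estimated correlation). Of 34 erythroid genes 21 rose and 3 fell (21 and 6 adjusted over the list alone), with the carbonic anhydrase gene Car1 95.1-fold higher but Trim10 3.25-fold lower (camera adjusted p = 1.1e-06, and adjusted p = 0.38 with an estimated correlation). Of 30 interferon response genes 23 fell (30 adjusted over the list alone; camera adjusted p = 2.55e-12, and adjusted p = 0.288 with an estimated correlation). Of 28 monocyte and macrophage genes 16 fell and 1 rose (23 and 1 adjusted over the list alone), with Cd68 2.22-fold lower and Fcgr3, also carried by mast cells, 2.38-fold higher (camera adjusted p = 2.89e-08, and adjusted p = 0.288 with an estimated correlation). Of 16 dendritic cell and MHC class II genes 13 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 1.52e-08; adjusted p = 0.25 with an estimated correlation). Of 25 innate immune receptor genes 9 fell (18 adjusted over the list alone), including Nod1, 1.76-fold (camera adjusted p = 4.84e-08, and adjusted p = 0.288 with an estimated correlation).

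In the lymphoid list 6 of 10 genes fell and 1, Il7r, rose 2.47-fold (8 and 1 adjusted over the list alone; camera adjusted p = 0.0028; adjusted p = 0.288 with an estimated correlation). Among 13 endothelial and stromal genes 6 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0114; adjusted p = 0.25 with an estimated correlation). Among 24 neutrophil genes 12 fell and 3 rose (14 and 3 adjusted over the list alone), with Cebpe, a granulocyte transcription factor gene, 3.53-fold higher (camera adjusted p = 0.0113, and adjusted p = 0.557 with an estimated correlation). That neutrophil call ended without enhancer-null empty-vector replicate 4 (camera adjusted p = 0.0545) and without replicate 4 of every group (0.165). The hepatocyte list (main value 0.164) was called as lower with the replicate number as a block (0.0184) and without enhancer-null empty-vector replicate 4 (0.0223) or GATA2 replicate 1 (0.0338). Not called were the stem and progenitor list, with 4 of 20 genes up and 1 down and the same adjusted over the list alone (camera adjusted p = 0.899), and the immediate early and heat shock list, with 4 of 18 up and 2 down (5 and 6 adjusted over the list alone; camera adjusted p = 0.893). In the first Myb rose 2.05-fold, and in the second Egr1 rose 3.50-fold. Mgll did not rise, at 2.14 ± 0.467 CPM (log2 difference -0.17, SE 0.19, adjusted p = 0.59).

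Genes that a vector moved back after enhancer loss were those called in both comparisons with opposite directions. Such a gene may stop short of its wild-type level or pass it. Epx passed it, at 287 CPM with wild-type GATA2 against 69.5 in wild-type cells. Wild-type GATA2 moved back 2202 of the 6859 genes, 32.1%: 1007 that had risen and 1195 that had fallen. R307W moved back 1869 (27.2%) and T354M 1633 (23.8%). Because the enhancer-null empty-vector libraries enter both comparisons, opposite directions can arise by themselves. Counting only changes of at least 2-fold, the numbers were 956, 693 and 589. Independent lists would share 666, 607 and 599 genes in this way. In 20 simulations without an effect the highest number was 0. Almost no gene is called there, so that number says nothing of the shared libraries. When the empty-vector libraries were split between the comparisons, medians over 6 splits were 933.5, 683 and 614 of 5300.5 genes (17.6, 12.9 and 11.6%), where independent lists from the same smaller fits would share 240, 198 and 206. Across genes the covariance of the 2 sets of log2 differences was -0.653, -0.487 and -0.333, against -0.064, -0.066 and -0.064 in the simulations. Leaving out the vector group's own replicate 4 lowered the numbers to 1217, 925 and 884, and without enhancer-null empty-vector replicate 4 those for R307W and T354M were 1194 and 1009. Without T354M replicate 1 the last was 1041.

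Wild-type GATA2 in enhancer-null cells was also set against wild-type cells with an empty vector, to see what remained different. Gata2 did not differ past the test, at 80.7 ± 37.3 and 44.3 ± 9.81 CPM (n = 4 and 4; log2 difference 0.86, SE 0.33, adjusted p = 0.051). It was called as higher with no filter on low counts (0.0152), by the DESeq2 test (0.0269), by limma on TPM (0.00351) and without GATA2 replicate 3 (0.0183). Lower were 30 of 34 erythroid genes, with Slc4a1 at 2.66 ± 1.12 against 264 ± 67.0 CPM and Trim10 79.9-fold lower. Higher were 5 of 10 eosinophil and 12 of 23 mast cell and basophil genes, with 2 of the latter lower. Epx was 4.13-fold, Mcpt8 7.96-fold and the basophil protease gene Prss34 12.8-fold higher. Mgll stayed 9.95-fold lower, at 2.14 ± 0.467 CPM.

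In this comparison 4869 genes differed, 30.7%, 2335 higher and 2534 lower. Log2 differences were -6.63 for Slc4a1 (SE 0.50, adjusted p = 2.38e-08), 3.68 for Prss34 (SE 0.69, adjusted p = 0.000469), 3.11 for Cd96 (SE 0.27, adjusted p = 1.18e-07) and -3.31 for Mgll (SE 0.19, adjusted p = 9.04e-10), with no overlap between the libraries of the groups. Of 34 erythroid genes 30 were lower (1 higher and 30 lower adjusted over the list alone; camera adjusted p = 2.25e-22; adjusted p = 0.306 with an estimated correlation), and so were 17 of 21 megakaryocyte genes with 1 higher (17 and 1 adjusted over the list alone; camera adjusted p = 4.91e-08; adjusted p = 0.411 with an estimated correlation). Among 24 neutrophil genes 16 were lower and 3 higher, equally adjusted over the list alone, with Camp 21.4-fold lower (camera adjusted p = 8.73e-07, and adjusted p = 0.411 with an estimated correlation). Cell cycle genes were lower for 15 of 30, and for 15 adjusted over the list alone (camera adjusted p = 7.35e-05, and adjusted p = 0.592 with an estimated correlation). Interferon response genes were still higher for 21 of 30 (23 adjusted over the list alone; camera adjusted p = 8.26e-06; adjusted p = 0.648 with an estimated correlation), as were 13 of 16 dendritic cell and MHC class II genes with 2 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.00047; adjusted p = 0.628 with an estimated correlation). Monocyte and macrophage genes were higher for 10 of 28 (10 higher and 1 lower adjusted over the list alone), with Cx3cr1 4.4-fold higher (camera adjusted p = 0.00735, and adjusted p = 0.691 with an estimated correlation). Eosinophil genes were higher for 5 of 10 (6 adjusted over the list alone; camera adjusted p = 0.00659; adjusted p = 0.648 with an estimated correlation). Of 74 named genes, 8 were no longer called without some single library, 6 of them without wild-type replicate 4, and Gata1 (1.87-fold lower, adjusted p = 0.0481) lost its call when any 1 of GATA2 replicates 1, 2 and 3 (0.101, 0.0985, 0.148) or wild-type replicates 1 to 4 (0.0697, 0.0627, 0.108, 0.0831) was left out.

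The other called lists in this comparison were less secure, and each call ended when any of the libraries named below was left out. Of 23 mast cell and basophil genes 12 were higher and 2 lower (12 and 3 adjusted over the list alone; camera adjusted p = 0.0307; adjusted p = 0.691 with an estimated correlation), and the call ended without GATA2 replicate 1 (0.059) or 4 (0.341), without wild-type replicate 1 (0.0669), 2 (0.0606) or 3 (0.0586), and without replicate 4 of every group (0.141). Of 10 lymphoid genes 2 were higher, and 2 adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.648 with an estimated correlation), and that call ended without GATA2 replicate 1 (0.0679) or 3 (0.07) or wild-type replicate 1 (0.0669) or 3 (0.0892). Innate immune receptor genes were higher for 10 of 25 and lower for 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0231; adjusted p = 0.691 with an estimated correlation), a call that ended without GATA2 replicate 1 (0.0532) or 3 (0.0709) or wild-type replicate 1 (0.0677) or 3 (0.0911). The hepatocyte list was lower (camera adjusted p = 0.0231, and adjusted p = 0.691 with an estimated correlation) with 1 of 13 members called and none adjusted over the list alone, and this call ended without GATA2 replicate 4 (0.12) or wild-type replicate 1 (0.114).

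R307W in enhancer-null cells was compared with the same cells with an empty vector to see which responses the N-terminal finger variant gave. Gata2 counts rose to 54.8 ± 23.7 from 5.79 ± 1.3 CPM (n = 4 and 4), 9.43-fold. All 10 eosinophil genes rose, among them the granule gene Prg3 at 230 ± 48.8 against 0.164 ± 0.114 CPM and the interleukin 5 receptor gene Il5ra 179-fold higher. Among mast cell and basophil genes Hdc rose 29.6-fold to 420 ± 107 CPM and Mcpt8 3.23-fold to 35.3 ± 16.5 CPM. Gata1 rose 6.63-fold and the erythroid gene Kel 14.0-fold. Kel was at 91.3 CPM in R307W replicate 4 and 14.6 to 42.3 in the others, against a mean of 2.97 with the empty vector. At the same time 12 of 28 monocyte and macrophage and 12 of 16 dendritic cell genes fell, such as Cx3cr1, 2.24-fold.

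With R307W 2773 genes changed, 17.5% of those tested, 1589 up and 1184 down, 1143 of them at least 2-fold. With the replicate number as a block the total was 4097, and 2769 of the 2773 were among them. Log2 differences were 3.24 for Gata2 (SE 0.36, adjusted p = 7.43e-06), 10.46 for Prg3 (SE 0.61, adjusted p = 3.41e-09), 6.72 for Epx (SE 0.79, adjusted p = 1.25e-05), 2.73 for Gata1 (SE 0.37, adjusted p = 5.37e-05) and 4.89 for Hdc (SE 0.34, adjusted p = 2.4e-08). Nepn, which encodes a small leucine-rich proteoglycan, had 7.24 ± 8.26 CPM and no counts in the empty-vector cells, at least 277-fold higher. Replicate 4 held 642 of its 878 counts, and without that library the bound was 108-fold. The collagen gene Col5a2 was lower, at -1.86 (SE 0.37, adjusted p = 0.00225), as was Acta2, at -1.77 (SE 0.37, adjusted p = 0.00306). All 4 libraries of one group lay above all 4 of the other for each of these genes. Without R307W replicate 4 the total was 1279 and 24 of 66 named genes were no longer called, without enhancer-null empty-vector replicate 4 it was 1756, and without replicate 4 of every group 1506, and the genes given values here kept their calls.

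The eosinophil list rose in all 10 genes, and 10 adjusted over the list alone (camera adjusted p = 1.11e-20, and adjusted p = 0.0483 with an estimated correlation). In the mast cell and basophil list 12 of 23 genes rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 9.75e-07; adjusted p = 0.298 with an estimated correlation), and erythroid genes rose for 17 of 34 and fell for 3 (18 and 4 adjusted over the list alone; camera adjusted p = 0.000556; adjusted p = 0.5 with an estimated correlation). Interferon response genes fell for 14 of 30 (26 adjusted over the list alone; camera adjusted p = 2.37e-10, and adjusted p = 0.298 with an estimated correlation). Monocyte and macrophage genes fell for 12 of 28 and rose for 1 (22 and 1 adjusted over the list alone; camera adjusted p = 1.72e-08; adjusted p = 0.298 with an estimated correlation). Dendritic cell and MHC class II genes fell for 12 of 16 (13 adjusted over the list alone), with H2-Eb1 2.90-fold lower (camera adjusted p = 1.61e-08, and adjusted p = 0.189 with an estimated correlation). Innate immune receptor genes fell for 9 of 25 (22 down and 1 up adjusted over the list alone; camera adjusted p = 4.64e-08; adjusted p = 0.298 with an estimated correlation). Lymphoid genes fell for 7 of 10 (9 adjusted over the list alone), among them the B cell factor gene Ebf1, 3.49-fold (camera adjusted p = 8e-06, and adjusted p = 0.129 with an estimated correlation). Megakaryocyte genes fell for 8 of 21 (12 adjusted over the list alone; camera adjusted p = 7.5e-05; adjusted p = 0.307 with an estimated correlation), and endothelial and stromal genes for 6 of 13 with 1 up (10 and 2 adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.129 with an estimated correlation).

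The last called lists with R307W were less secure. Immediate early and heat shock genes fell for 2 of 18, and 2 adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.307 with an estimated correlation), and the call ended without enhancer-null empty-vector replicate 4 (0.0914), R307W replicate 1 (0.0686) or replicate 4 of every group (0.0932). The hepatocyte list was lower (camera adjusted p = 0.00641, and adjusted p = 0.528 with an estimated correlation), with none of its 13 genes called over all genes or adjusted over the list alone, as in every comparison among the enhancer-null groups. That call ended without R307W replicate 4 (0.11). The neutrophil list was not called in the main analysis (0.0864) but was called as lower with the replicate number as a block (0.00871). It was also called with no filter on low counts (0.0463) and without enhancer-null empty-vector replicate 1 (0.0319) or 3 (0.0246) or R307W replicate 2 (0.00479). Myb rose 2.65-fold and Gfi1 1.95-fold, to 22.3 ± 2.52 CPM.

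T354M in enhancer-null cells was compared with the empty vector in the same way, for the variant of the C-terminal finger. Gata2 counts rose to 52.0 ± 19.7 from 5.79 ± 1.3 CPM (n = 4 and 4), 8.96-fold. Of 10 eosinophil genes 9 rose, with Epx at 536 ± 454 (1170 in replicate 4, 186 to 567 in the others) against 0.114 ± 0.129 CPM and Il5ra at 55.5 ± 27.1 CPM, 263-fold higher. Of 24 neutrophil genes 7 rose and 1 fell: Gfi1 went from 11.5 ± 1.42 to 62.5 ± 7.82 CPM and Ctsg, a granule protease gene, from 233 ± 34.0 to 843 ± 149 CPM. Erythroid genes fell for 15 of 34 and rose for 4, and Slc4a1 fell 4.86-fold to 1.75 ± 0.860 CPM and Trim10 4.54-fold. These 2 genes were lower with the other vectors too. Slc4a1 was at 8.42 CPM with the empty vector, 2.66 with wild-type GATA2 and 2.86 with R307W. Trim10 was at 1.10, 0.336 and 0.309 CPM. The interferon response gene Irf9 fell 2.12-fold.

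In total 2751 genes changed with T354M, 17.4% of those tested, 1467 up and 1284 down, and 1046 changed at least 2-fold. With the replicate number as a block the total was 3804, and 2745 of the 2751 were among them. Log2 differences were 3.16 for Gata2 (SE 0.36, adjusted p = 6.65e-06), 12.20 for Epx (SE 0.79, adjusted p = 5.17e-09), 2.45 for Gfi1 (SE 0.11, adjusted p = 2.21e-10), 3.25 for Cebpe (SE 0.35, adjusted p = 2.87e-06), 1.73 for Myb (SE 0.12, adjusted p = 9.97e-09) and -2.28 for Slc4a1 (SE 0.46, adjusted p = 0.00235). Cd7 fell by 1.90 on the log2 scale (SE 0.40, adjusted p = 0.00344). For these genes all 4 libraries of one group lay above all 4 of the other. Gata1 rose 2.21-fold to 12.2 ± 6.62 CPM (adjusted p = 0.034), with overlapping libraries, and was not called without T354M replicate 1 (adjusted p = 0.0741) or 4 (0.182), or without enhancer-null empty-vector replicate 1 (0.0759), 2 (0.0712) or 3 (0.0937). The total was 1448 without T354M replicate 4, when 22 of 74 named genes were no longer called, and 1764 without T354M replicate 1, 1732 without enhancer-null empty-vector replicate 4 and 1669 without replicate 4 of every group.

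Eosinophil genes rose for 9 of 10, and 9 adjusted over the list alone (camera adjusted p = 2.3e-17, and adjusted p = 0.0795 with an estimated correlation). In the mast cell and basophil list 10 of 23 genes rose and 2 fell (10 and 3 adjusted over the list alone), with Cpa3 26.5-fold and Hdc 27.0-fold higher (camera adjusted p = 0.00109, and adjusted p = 0.413 with an estimated correlation). Neutrophil genes rose for 7 of 24 and fell for 1, as they did adjusted over the list alone (camera adjusted p = 0.00641, and adjusted p = 0.413 with an estimated correlation). Erythroid genes fell for 15 of 34 and rose for 4 (19 and 5 adjusted over the list alone; camera adjusted p = 0.00017; adjusted p = 0.413 with an estimated correlation). Megakaryocyte genes fell for 9 of 21 (12 down and 2 up adjusted over the list alone), with Plek 1.59-fold lower (camera adjusted p = 6.34e-05, and adjusted p = 0.33 with an estimated correlation). Interferon response genes fell for 25 of 30 (30 adjusted over the list alone; camera adjusted p = 4.46e-14, and adjusted p = 0.286 with an estimated correlation). Monocyte and macrophage genes fell for 11 of 28 and rose for 1 (19 and 1 adjusted over the list alone), with Cx3cr1 2.73-fold lower (camera adjusted p = 6.9e-08, and adjusted p = 0.295 with an estimated correlation). Dendritic cell and MHC class II genes fell for 15 of 16 (16 adjusted over the list alone), with Cd74 2.98-fold lower (camera adjusted p = 6.49e-10, and adjusted p = 0.131 with an estimated correlation).

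Further lists that fell with T354M were the innate immune receptors, 9 of 25 with Clec12a up 2.42-fold (20 and 1 adjusted over the list alone; camera adjusted p = 8.69e-07; adjusted p = 0.33 with an estimated correlation), and the lymphoid genes, 5 of 10 (9 adjusted over the list alone; camera adjusted p = 2.66e-05; adjusted p = 0.131 with an estimated correlation). Endothelial and stromal genes fell for 7 of 13 and rose for 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000167; adjusted p = 0.0795 with an estimated correlation). Immediate early and heat shock genes fell for 3 of 18 (8 adjusted over the list alone), among them Nr4a1, 2.46-fold (camera adjusted p = 0.000322, and adjusted p = 0.23 with an estimated correlation). Cell cycle genes rose for 3 of 30, none of them past the test adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.457 with an estimated correlation), and that call ended without enhancer-null empty-vector replicate 4 (0.0614), T354M replicate 3 (0.102) or 4 (0.106), or replicate 4 of every group (0.212). The hepatocyte list (main value 0.115) was called as lower with the replicate number as a block (0.00919) and without enhancer-null empty-vector replicate 4 (0.0107) or T354M replicate 1 (0.00887).

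**Figure D3:**
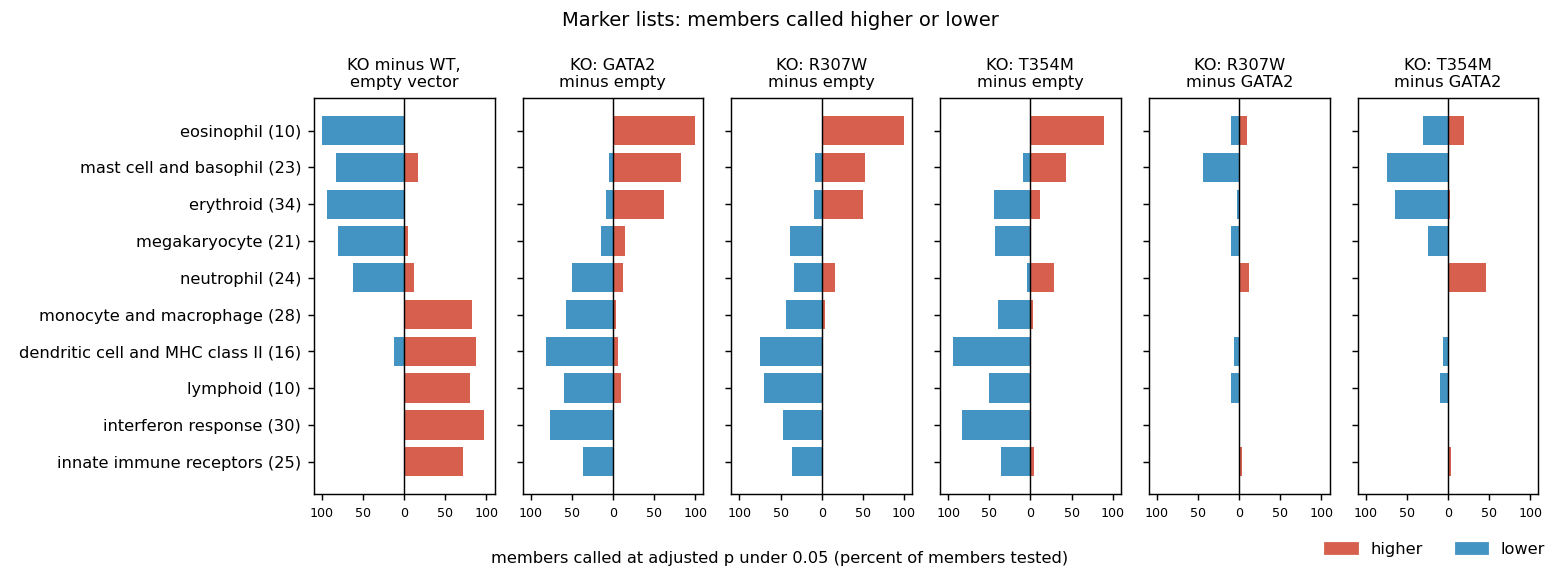
Percent of the tested members of 10 gene lists called higher (right of 0) or lower (left of 0) in each of 6 comparisons, 1 bar pair per list and comparison, where WT is wild-type and KO is enhancer-null. Erythroid genes were lower for 15 of 34 with T354M and higher for 17 of 34 with R307W, both against the empty vector.

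R307W was set against wild-type GATA2 in the same enhancer-null cells to test the variant itself. Gata2 counts did not differ past the test, at 54.8 ± 23.7 and 80.7 ± 37.3 CPM (n = 4 and 4; log2 difference -0.56, SE 0.32, adjusted p = 0.752). With R307W 10 of 23 mast cell and basophil genes were lower: Mcpt8 was 18.2-fold lower at 35.3 ± 16.5 against 644 ± 337 CPM, and Cpa3 6.44-fold lower. Tpsb2 had 0.00964 ± 0.0193 against 11.3 ± 13.4 CPM, a ratio whose exact 95% counting interval ran from 226 to 50000, and from 95.2 to 21100 without GATA2 replicate 4, which held 894 of 1296 counts. The eosinophil list did not move as a group, but Epx was 24.0-fold lower, at 11.9 ± 4.66 against 287 ± 74.4 CPM. Ces1d, a carboxylesterase gene, was 16.9-fold higher with R307W, at 22 ± 9.67 CPM.

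Between R307W and wild-type GATA2 274 genes differed, 1.7% of those tested, 93 higher and 181 lower. Log2 differences were -4.58 for Epx (SE 0.50, adjusted p = 8.81e-05), -4.19 for Mcpt8 (SE 0.42, adjusted p = 5.79e-05), -2.69 for Cpa3 (SE 0.39, adjusted p = 0.000817), -2.32 for Il7r (SE 0.29, adjusted p = 0.000259), 4.07 for Ces1d (SE 0.36, adjusted p = 1.62e-05) and 2.08 for Klhl3 (SE 0.24, adjusted p = 0.000112), each with all 4 libraries of one group above all 4 of the other. Of 23 mast cell and basophil genes 10 were lower (18 adjusted over the list alone), and this list held under both correlations (camera adjusted p = 7.97e-27, and adjusted p = 0.0375 with an estimated correlation). Megakaryocyte genes were lower for 2 of 21 (4 adjusted over the list alone; camera adjusted p = 3.38e-08; adjusted p = 0.339 with an estimated correlation) and immediate early and heat shock genes for 3 of 18 (4 adjusted over the list alone; camera adjusted p = 0.00158; adjusted p = 0.339 with an estimated correlation). The erythroid list was lower with 1 of 34 called (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00054; adjusted p = 0.772 with an estimated correlation), a call that ended without GATA2 replicate 4 (0.269). Eosinophil genes were higher for 1 and lower for 1 of 10 (3 and 1 adjusted over the list alone; camera adjusted p = 0.576).

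The number of genes that differed between R307W and wild-type GATA2 depended on single libraries. It was 126 without GATA2 replicate 4, 177 without GATA2 replicate 1, 156, 164 and 163 without R307W replicates 1, 2 and 3, and 162 without replicate 4 of every group. With the replicate number as a block it was 441, 267 of them among the 274. The hepatocyte list (main value 0.0672) was then called as lower (camera adjusted p = 0.000546). It was also called with no filter on low counts (0.0237) and without GATA2 replicate 4 (0.000655) or R307W replicate 1 (0.000582) or 2 (0.0309). From the 8 libraries of these groups alone it was 105 and by DESeq2 430. Without replicate 4 of either GATA2 or every group, 8 of the 22 named genes called were no longer called, none of them given a value here.

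T354M against wild-type GATA2 gave more differences than R307W did. Gata2 counts were 52.0 ± 19.7 and 80.7 ± 37.3 CPM (n = 4 and 4), not past the test (log2 difference -0.63, SE 0.32, adjusted p = 0.28). With the replicate number as a block Gata2 was called as lower with T354M (log2 difference -0.62, adjusted p = 0.028). The block over the 16 enhancer-null libraries alone gave a log2 difference of -0.63 (edgeR adjusted p = 0.0112). With T354M 22 of 34 erythroid genes were lower and 1 higher, with Kel 16.6-fold and Gata1 3.97-fold lower, the latter at 12.2 ± 6.62 against 48.6 ± 18.2 CPM. So were 17 of 23 mast cell and basophil genes, with Mcpt8 11.5-fold lower. Tpsb2 had 5 counts with T354M, all in replicate 4, against 1296. Of 24 neutrophil genes 11 were higher, with Gfi1 at 62.5 ± 7.82 against 15.8 ± 1.04 CPM and Ctsg 3.15-fold higher. Epx, at 536 ± 454 and 287 ± 74.4 CPM, did not differ past the test (adjusted p = 0.232).

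Of all genes tested, 1583 differed between T354M and wild-type GATA2, 10% of them, 611 higher and 972 lower, with 728 at least 2-fold. With the replicate number as a block 2090 differed, and 1575 of the 1583 were among them. Log2 differences were 1.98 for Gfi1 (SE 0.11, adjusted p = 6.34e-09), -1.99 for Gata1 (SE 0.35, adjusted p = 0.000835), -3.52 for Mcpt8 (SE 0.41, adjusted p = 2.23e-05), -2.50 for Egr1 (SE 0.39, adjusted p = 0.000274), 3.30 for the chloride channel gene Cftr (SE 0.31, adjusted p = 2.94e-06) and 2.22 for the deiodinase gene Dio2 (SE 0.21, adjusted p = 2.39e-06), with no overlap between the libraries of the groups. Of 34 erythroid genes 22 were lower and 1 higher (23 and 1 adjusted over the list alone; camera adjusted p = 2.81e-20; adjusted p = 0.132 with an estimated correlation). Of 23 mast cell and basophil genes 17 were lower (18 adjusted over the list alone; camera adjusted p = 2.61e-19; adjusted p = 0.127 with an estimated correlation). Of 24 neutrophil genes 11 were higher (16 adjusted over the list alone), among them Ngp, 4.38-fold (camera adjusted p = 8.36e-12, and adjusted p = 0.132 with an estimated correlation). Megakaryocyte genes were lower for 5 of 21 (6 adjusted over the list alone; camera adjusted p = 0.000116; adjusted p = 0.539 with an estimated correlation), and immediate early and heat shock genes for 5 of 18 (7 adjusted over the list alone; camera adjusted p = 0.00104; adjusted p = 0.323 with an estimated correlation). Eosinophil genes were higher for 2 and lower for 3 of 10, and the same adjusted over the list alone (camera adjusted p = 0.359). That list was called as lower without T354M replicate 4 (0.00926) or replicate 4 of every group (0.0294). Without GATA2 replicate 4 the number of genes was 983 and 7 of 38 named genes were no longer called, and without replicate 4 of every group 1014 and 8, and the genes given values here kept their calls.

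The variants were then compared with each other. Gata2 counts were nearly equal, at 54.8 ± 23.7 CPM with R307W and 52.0 ± 19.7 with T354M (n = 4 and 4; log2 difference 0.07, SE 0.32, adjusted p = 0.992). Higher with R307W were 17 of 34 erythroid genes, with Kel at 41.8 ± 35.2 (91.3 in replicate 4, 14.6 to 42.3 in the others) against 1.54 ± 0.407 CPM and Car1 6.07-fold higher. Of 24 neutrophil genes 6 were lower, including Gfi1, 2.80-fold, and Ctsg, 3.88-fold. Epx was 44.8-fold lower with R307W, at 11.9 ± 4.66 against 536 ± 454 CPM. Not every eosinophil gene went that way. Ear2, an eosinophil ribonuclease gene chosen after its values were seen, was 15.1-fold higher with R307W (edgeR adjusted p = 0.000231). Its level was 270 ± 144 against 17.8 ± 14.7 CPM. The eosinophil list was not called (camera adjusted p = 0.129, direction higher with R307W).

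The variants differed in 553 genes, 3.5% of those tested, 364 higher and 189 lower with R307W, and 309 of them at least 2-fold. Log2 differences were 4.76 for Kel (SE 0.54, adjusted p = 5.25e-05), 4.69 for Ces1d (SE 0.38, adjusted p = 1.02e-06), -5.49 for Epx (SE 0.52, adjusted p = 5.42e-06), -4.42 for the interleukin 17 receptor gene Il17rb (SE 0.56, adjusted p = 0.000135) and -1.48 for Gfi1 (SE 0.11, adjusted p = 3.61e-07), with no overlap between the libraries of the groups. T354M replicate 4 held 533 of the 967 Il17rb counts with T354M, at 17.2 CPM against 3.28 to 8.70 in the others. Of 34 erythroid genes 17 were higher with R307W (20 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.01e-24; adjusted p = 0.126 with an estimated correlation). Of 24 neutrophil genes 6 were lower (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.49e-14; adjusted p = 0.126 with an estimated correlation). The mast cell and basophil list had 4 genes higher and 1 lower of 23 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.904 with an estimated correlation), and this call ended without T354M replicate 2 (0.0926) or 3 (0.0559) and with these 8 libraries alone (0.124). With the replicate number as a block 888 genes differed, 550 of them among the 553. The hepatocyte list (camera adjusted p = 0.00661, main value 0.134) was then called as lower and the interferon response list (0.0139, main value 0.0766) as higher. Without R307W replicate 1 (0.00419) or T354M replicate 4 (0.00639) the hepatocyte list was called too. So was the interferon list with no filter on low counts (0.00939) and without R307W replicate 4 (7.86e-09), T354M replicate 1 (0.0297), 2 (0.00158) or 3 (0.0194), or replicate 4 of every group (0.000104). The number of genes was 284 without R307W replicate 4, 365 without R307W replicate 1, 316 without replicate 4 of every group, 244 from the 8 libraries alone and 360 by limma on TPM.

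Responses of the 3 proteins were also compared gene by gene. Of the 3042 genes that changed with wild-type GATA2, 1923 (63.2%) changed in the same direction with R307W and 1392 (45.8%) with T354M, and of the 2773 for R307W 1661 (59.9%) did so with T354M. These comparisons share the empty-vector libraries, which by themselves give shared directions. Independent lists would share 272, 267 and 243 genes. The highest of 20 simulations was 1, but almost no gene is called in them, so that number says nothing of the shared libraries. Medians over 6 splits of the empty-vector libraries were 618, 410 and 501.5 (45.1, 29.8 and 44.1%), beside 60, 63 and 51 for independent lists from those smaller fits. Covariances across genes were 0.586, 0.415 and 0.433, against 0.066, 0.064 and 0.065 in the simulations.

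Of the 3042 genes that changed with wild-type GATA2, 166 (5.5%) differed under R307W and 751 (24.7%) under T354M against the direction of the GATA2 response. Here the wild-type GATA2 libraries enter both comparisons. Independent lists would share 28 and 157. In the 20 simulations the highest number was 0, with almost no gene called, which says nothing of the shared libraries. Covariances across genes were -0.182 and -0.353, against -0.061 in the simulations for both. Medians over 6 splits of those libraries were 58.5 (36 to 134) and 370.5 (283 to 389), beside 6 and 49 for independent lists from those smaller fits. For R307W the number was 67, 106 and 271 without GATA2 replicates 4, 1 and 3, and 86, 87 and 87 without R307W replicates 1, 2 and 3. It was 261 with the replicate number as a block and 51 from the libraries of each comparison alone. For T354M it was 1052 with the block, 402 and 936 without GATA2 replicates 4 and 3. The block over the 16 enhancer-null libraries gave 377 for R307W and 1484 for T354M.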

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

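The tests with Gata2 as a covariate, without replicate 4, on the globin genes, on the empty-vector libraries and on slopes were chosen only after the result was seen, while the regrouping of libraries was planned. In 56 genes that the text names, the values of each group with at least 40 counts were searched for a library farther from the others than Dixon's criterion for 4 values allows. Of 261 such groups of values 17 had one, where chance alone gives about 1 in 20, or 13.1, and 5 of the 17 were in a replicate 4.

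With R307W, replicate 4 stood apart for Hdc (580 CPM, nearest other 373), Cd79b (7.52, below the others) and Prss34 (166), replicate 2 for Camp (32.9) and Ngp (68.7), and replicate 3 for Cd96 (10.9). With T354M, replicate 2 was below the others for Gfi1 (50.9), replicate 1 below them for Ccne1 (21.8), and replicate 3 above them for Acta2 (4.18). With wild-type GATA2, replicate 3 was above the others for Mycl (4.16) and replicate 2 for Ngp (49.4). In enhancer-null cells with an empty vector, replicate 1 was below the others for Cpa3 (9.36), and replicate 4 above them for Clec1b (10.3) and Cebpe (7.67). In wild-type cells, replicate 2 was above the others for Itgax (2.80) and Cd79b (6.82), and replicate 1 for Acta2 (12).

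A difference between groups under the same contrast, tested directly, was seen for R307W against wild-type GATA2 (274 genes), T354M against wild-type GATA2 (1583 genes) and R307W against T354M (553 genes). Whether chance can give such numbers was examined with edgeR on the 8 libraries of each comparison in all 35 splits into 4 and 4. For enhancer loss and for GATA2 against wild-type cells only 1 of the 35 splits, the real one, gave as many genes (5982 and 3635, highest other 0 both times). This argues against chance there only if the numbers do not tie wild-type libraries to the others. Between wild-type and enhancer-null empty-vector libraries the mean same-numbered correlation was 0.16, against -0.05 for other pairs, so a tie is not excluded. In the other 6 comparisons the replicate numbers tie the libraries of the groups, so that the splits to compare are the 8 that part all 4 pairs, too few for a share under 0.05. The 35 splits, planned as the test, treat tied libraries as free to change places, and 1 of them, the real one, gave as many genes in each. The real numbers were 3813, 3199 and 2989 for GATA2, R307W and T354M against the empty vector, with a highest other of 0, and 105, 1157 and 244 for the 3 comparisons above, with a highest other of 1, 1 and 20 (among the 8 splits 0, 1 and 0).

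Of 23 mast cell and basophil genes, 10 were lower with R307W and 17 with T354M than with wild-type GATA2. With an estimated correlation the list was called for R307W (camera adjusted p = 0.0375) but not for T354M (0.127). A lower Gata2 level in the variant libraries was examined with log2 Gata2 as a covariate in the 12 vector libraries. The median log2 difference of the called members went from -5.04 (MAD 3.11) to -3.83 (MAD 2.65) for R307W. For T354M it went from -3.54 (MAD 2.53) to -2.79 (MAD 2.24). Most of the difference stayed, but these members were chosen as called lower in the same comparisons. Gata2 was also higher in replicate 4 of the vector groups, so the covariate cannot be separated from the replicate number. The Gata2 level as a cause is therefore not settled. Without GATA2 replicate 4, the library with the most Gata2, 5 of the 10 members stayed called for R307W (median -3.98) and 16 of 17 for T354M (median -3.11), so that library alone does not account for the difference, although 5 calls for R307W rest on it. The amount of GATA2 protein was not measured, and the later deposit of the variant libraries stays open as a difference in handling. Not all members moved alike: Hdc had 568, 420 and 384 CPM with wild-type GATA2, R307W and T354M. A candidate explanation, not tested here, is a lower activity of both variants at mast cell genes. Counts over a whole culture cannot separate this from a lower share of mast cells or basophils.

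Of 34 erythroid genes 17 were higher with R307W than with T354M at nearly equal Gata2 counts. The list was not called with an estimated correlation (camera adjusted p = 0.126). At the slope of each gene on log2 Gata2 within the vector groups, even the upper 95% end of the Gata2 difference (0.71) would bring a median of 0.63 (MAD 0.15) over the 17 called members, against the 2.53 (MAD 0.61) seen. For these members this argues against the level of Gata2 counts as the whole cause, but the amount of GATA2 protein was not measured. These members were also chosen as called in this comparison, and the slope cannot be separated from replicate 4, which had more Gata2. Red cells or their RNA carried over from the liver bring globin transcripts above all. All 4 globin genes were higher with R307W, by a median of 0.74, and Hbb-bt was called (log2 difference 2.10, edgeR adjusted p = 0.0202). That median lay below that of the called members, but those were chosen as called in this comparison and the globin genes were not. So the globin genes do not decide on such a carry-over. Without replicate 4 of every group 16 of the 17 stayed called (median 2.27). Both variant groups come from the same set of records, so the labels give no difference in handling between them. A candidate explanation, not tested here, is a weaker erythroid activity of T354M than of R307W. Counts over a whole culture cannot separate this from a lower share of erythroid cells.

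Replicate 4 of the 3 vector groups differed from replicates 1 to 3 in 2969 genes, by a median of 0.66 on the log2 scale. If the cells of replicate 4 differed with or without a GATA2 vector, the empty-vector replicate 4 would deviate alike: its deviation in the same direction had a median of 0.13 (MAD 0.30), with 68.5% of genes on the same side. The genes were chosen for replicate 4 of the vector groups, and only 1 library stands for the empty vector. So this does not decide on such cells as a cause. With the empty vector, the mean log2 CPM of the erythroid list, centred per gene, was -0.27 in replicate 4 and -1.36 to -0.91 otherwise. The hepatocyte list had -0.83 against 0.22 to 1.21, and the interferon response list 1.21 against 1.08 to 1.73. Erythroid and hepatocyte genes thus moved as in replicate 4 of the vector groups, and interferon response genes did not. If the higher Gata2 level of replicate 4 were the source, genes would follow Gata2 within replicates 1 to 3 as well: 74.2% of 2968 genes did so in sign, against 56.5% of 12866 other genes. The Gata2 level stays open as well, since the genes were chosen for replicate 4 and Gata2 level and replicate number go together in 3 libraries. No biological explanation other than the Gata2 level was tested.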

How the results depend on the processing

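Leaving out replicate 4 of all groups, the block over the 16 enhancer-null libraries and protein-coding genes alone were tests chosen only after the data were seen; the other alternatives were planned. No called value of a named gene changed direction under any of them. Some lists that were not called did turn. For R307W against GATA2 the monocyte and macrophage list and the innate immune receptors (lower, 0.927 both) were called as higher without R307W replicate 4 (0.0177 and 0.0163) and as lower without GATA2 replicate 4 (0.0347 and 0.0312). The monocyte and macrophage list between the variants (lower, 0.776) was called as higher without R307W replicate 4 (0.0498). Of 468 values of named genes that were called, 463 kept the call with DESeq2 size factors, 462 with the DESeq2 test, 457 without a filter, 463 with the block, 431 with the 8 libraries compared, 418 with limma on TPM and 386 without replicate 4 of all groups. Over each library left out in turn 3316 of 3744 did, and 446 of 446 with protein-coding genes and 302 of 302 with the block over 16 libraries. DESeq2 size factors and protein-coding genes alone kept every count of genes and lists within 1.5 times. Except where a reason is given, the cause of the changes below was not tested.

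Between wild-type cells and the enhancer-null groups the libraries share only a number, and not every library correlated best with its own number. There the block called the endothelial and stromal list as higher on enhancer loss (0.0298, main value 0.055) and Gata2 as higher with GATA2 than in wild-type cells (0.00243, main value 0.051). It changed no other list call than this one and those given with the results. The block over the 16 enhancer-null libraries changed the same list calls as the block did among those groups.

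More lists that were not called became called, each in its main direction. Cell cycle genes were then higher for GATA2 against the empty vector (0.0963; no filter 0.00283, 8 libraries 0.0454, without empty-vector replicate 2 0.0328) and for R307W (0.0864; no filter 0.00402, without empty-vector replicate 2 0.0301, without R307W replicate 1 0.049). Immediate early genes were higher for GATA2 against wild-type cells with no filter (0.02, main value 0.392).

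For R307W against GATA2 the interferon list was higher (0.26; without GATA2 replicate 3 0.00879, R307W replicate 4 3.57e-06, replicate 4 of all groups 0.0142). Dendritic cell genes were higher (0.927; without R307W replicate 4 0.045). Neutrophil genes were higher (0.0672) with no filter (0.0259), protein-coding genes (0.0414) and without GATA2 replicate 2 (0.00343) or R307W replicate 1, 3 or 4 (0.0119, 0.0153, 0.0163). Lymphoid genes were lower (0.0725) with no filter (0.0129) and without GATA2 replicate 4 (0.0014) or R307W replicate 1 or 3 (0.0119, 0.0374). Stem and progenitor genes were lower (0.0672) with no filter (0.0214), 8 libraries (0.0248) and without GATA2 replicate 2 or 4 (0.0406, 0.0312) or R307W replicate 1 or 3 (0.0455, 0.0239).

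For T354M against GATA2 the endothelial list was lower (0.196) with no filter (0.0376) and without T354M replicate 2 (0.0451), and the interferon list (0.562) without GATA2 replicate 4 (0.00201). Between the variants eosinophil genes were higher with R307W (0.129) with no filter (0.0439) and without R307W replicate 3 (0.0168), T354M replicate 4 (0.000771) or replicate 4 of all groups (0.0191). Immediate early genes were higher (0.133) with no filter (0.0439) and without R307W replicate 1 or 4 (0.0347, 0.0498) or T354M replicate 2 (0.044), and dendritic cell genes (0.565) without R307W replicate 4 (0.0348). Gata2 neighbours were lower (0.129) without R307W replicate 4 (0.0498) or T354M replicate 1 (0.027), and innate receptors (0.565) without T354M replicate 4 (0.016).

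With the replicate number as a block, 441 genes differed between R307W and GATA2 and 888 between the variants, 261 response genes differed under R307W, and 5 lists were called between the variants. Over the 16 enhancer-null libraries the block gave 5293, 5345 and 4993 genes for GATA2, R307W and T354M against the empty vector, 657 and 2917 for R307W and T354M against GATA2, 1302 between the variants, 377 and 1484 response genes that differed under R307W and T354M, and 5 lists between the variants. Without replicate 4 of all groups, with fewer libraries, these gene counts were 1998, 1506, 1669, 162, 1014 and 316, the numbers moved back by R307W and T354M 1088 and 1024, and the lists between the variants 5.

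From the 8 libraries alone, with fewer degrees of freedom, 105 genes differed between R307W and GATA2, 244 between the variants and 51 response genes under R307W. The DESeq2 test gave 430 genes for R307W against GATA2. Limma on TPM gave 1831 genes for T354M against the empty vector, 360 between the variants, and 1191 and 986 moved back by R307W and T354M. A fold change of at least 2 left 2972, 1340, 1143, 1046, 728, 309 and 2002 genes for enhancer loss, GATA2, R307W and T354M against the empty vector, T354M against GATA2, R307W against T354M, and GATA2 against wild-type cells. It left 956, 693 and 589 moved back and 421 response genes that differed under T354M. Splitting the shared libraries, which leaves 2 per comparison, gave 933.5, 683 and 614 moved back and 58.5 and 370.5 response genes that differed.

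With an estimated correlation, camera called 1 list each for GATA2 and R307W against the empty vector and R307W against GATA2, and 0 in the other 5 comparisons, where the preset called 11, 13, 5, 3 and 12 and fry 13, 11, 4, 2 and 8. Fry called 1 list for R307W against GATA2, and without a filter 8 were called there and 6 between the variants.

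Leaving out each library in turn gave 1588 to 3395 genes for GATA2, 1279 to 2993 for R307W and 1448 to 3102 for T354M against the empty vector. It gave 126 to 368 for R307W and 983 to 1672 for T354M against GATA2, and 284 to 578 between the variants. Moved back were 1217 to 2490 by GATA2, 925 to 2035 by R307W and 884 to 1857 by T354M, and 67 to 271 and 402 to 936 response genes differed under R307W and T354M. Lists called were 4 to 9 for R307W against GATA2 and 3 to 8 between the variants. Enhancer loss gave 6196 to 6848 genes and GATA2 against wild-type cells 4125 to 5069. Depth limits genes with few counts, such as Tpsb2 and Nepn, whose ratios are bounds, wide intervals or rest on few counts.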

Other observations

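The genes in this part were chosen after their values were seen, and no test beyond the comparisons above was added for them. Some genes were higher with both variants than with wild-type GATA2. Ncam1, an adhesion molecule gene, had 25.3 CPM with wild-type GATA2, 69.8 with R307W and 70.4 with T354M (means, n = 4 each), log2 differences of 1.47 (adjusted p = 8.81e-05) and 1.48 (adjusted p = 1.04e-05). Mpo, which encodes myeloperoxidase, had 1864, 3413 and 4532 CPM, log2 differences of 0.87 (adjusted p = 0.00603) and 1.28 (adjusted p = 5.04e-05). Mgam had 8.05, 29.5 and 35.1 CPM. Wild-type cells with an empty vector had 27.6 CPM of Mgam, 49.9 of Ncam1 and 1359 of Mpo. So Mgam with the variants was near its wild-type level, while Mpo was above it.

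Other genes stood out with T354M. Anxa1 had 2239 CPM with T354M, a log2 difference of 1.53 to wild-type GATA2 (adjusted p = 8.74e-05), and Lin28a, a fetal progenitor RNA-binding protein gene, 27.3 CPM, a difference of 1.66 (adjusted p = 1.57e-05). The cytokine gene Osm was highest with wild-type GATA2, at 62.6 CPM against 15.4 with R307W (log2 difference -2.02, adjusted p = 0.000457) and 7.72 with T354M (-3.02, adjusted p = 2.94e-06). Il6 was lower with T354M (6.99 against 67.6 CPM, log2 difference -3.26, adjusted p = 0.00026), while with R307W it did not differ past the test (25.8 CPM, adjusted p = 0.201). Wild-type cells with an empty vector had 717 CPM of Anxa1, 18.4 of Lin28a, 20.8 of Osm and 14.3 of Il6. Among monocyte factor genes, Irf8 was 7.74-fold higher after loss of the enhancer (adjusted p = 6.92e-05).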
